A study of Danio rerio and Mus musculus and Xenopus tropicalis with 30 samples.

How the data were processed

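The series held 30 samples, of which 12 had processed files used here, 2 in each of 6 groups: RNA-seq of zebrafish tet1/2/3 morphants and wild type, RNA-seq of mouse embryos at E9.5 and E14.5, and ATAC-seq of zebrafish morphants and wild type. The other 18 samples, bisulfite and Tet-assisted bisulfite libraries, were not analysed here. Zebrafish were of mixed AB and Tübingen background at 24 hpf, and mice were of the CD1 strain, per the labels. RNA libraries were polyA-selected and strand-specific, made by the dUTP method, per the labels' protocols. Whether reads were counted by strand was not given in the sources used here.

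The deposited RNA files held estimated counts and TPM per gene, per the file headers, and kallisto was named in the submitters' processing notes, with no version. The gene annotation was not given in the sources used here. The mm10 build was listed for a single mouse RNA library, per the submitters' processing notes. TPM, transcript abundances relative to the library's total, were deposited values scaled within each library by effective length, which was the gene length minus 75 bases in zebrafish and minus 50 in mouse. Estimated counts were used as deposited after rounding to whole numbers. The deposited ATAC files listed read positions in danRer7 coordinates, per the submitters' processing notes, with the fragment length in a separate column. Fragments in the files were 41 to 99 bp long, and the aligner, duplicate removal and any position shift were not given in the sources used here. Entries were 10 bases wide in 3 libraries and 1 base wide in wild-type replicate 1, which was therefore processed differently before deposit. Opposite strands were offset by -49 bases in each library, and no further shift was applied. The labels' protocols gave 10 embryos and 13 PCR cycles per ATAC library.

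Gene symbols came from a reference table of identifiers and symbols, which matched 21699 of 22105 mouse and 0 of 31373 zebrafish identifiers. Zebrafish genes are therefore given by identifier, at most 2 that rose and 2 that fell, and the 28 zebrafish gene lists and the tet1, tet2 and tet3 transcripts were not analysed here. No genome annotation was used for the ATAC windows.

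Designs, gene lists, the rule for named genes and a set of alternative settings were fixed before the data were examined. The design named limma on log2(TPM + 1) unless the files held counts. They held estimated counts, so edgeR's quasi-likelihood test with TMM scaling was used (edgeR 4.0.16, R 4.3.3), on genes with a mean of at least 1 TPM, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences were coded morphant minus wild type and E14.5 minus E9.5. The coefficient of variation between replicates was 17.6% in zebrafish and 1.93% in mouse. Of the 34 mouse lists, 31 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 31 lists. Camera compares a list with all other genes, and fry tests whether a list moves one way on balance without such a comparison.

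The ATAC read ends were counted in 500 bp windows on chromosomes 1 to 25 after fragments with equal positions were reduced to 1, which left 39240822 and 20337986 read ends in morphants and 73149386 and 11846137 in wild type. Accessible windows had a mean over the 4 libraries of at least 5 times the uniform level. They were tested with limma-voom after median ratio scaling, and with edgeR as a tool added after the data were seen. Mitochondrial reads made up 0.989% to 4.02% and unplaced scaffolds 3.58% to 4.54% of read ends. The share of reads in accessible windows was compared by an exact permutation test of the difference in means.

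Named genes were the tet genes, the 10 highest and 10 lowest called genes by log2 difference with non-overlapping groups, a symbol and at least 5 TPM in the higher group, and up to 4 called members of each list with the largest log2 difference. A gene that this rule names is not reported here. In zebrafish the 2 highest and 2 lowest of these were given, and in ATAC the 3 highest and 3 lowest called windows. Genes with 0 reads in a group were given a lower bound of fold against a floor of 3 counts over the group. Genes with only a few reads in a group kept the fitted log2 difference, whose size is uncertain. Among them were Cdx4, Msgn1, Dmp1, Myh4, Neurod2, Krt4, Gdf5 and Hoxc12. Floors cover counting error only, because reads without molecular identifiers are not independent molecules.

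The scripts were tested on simulated data with 200 changed genes or windows. Each gene or window was given the same dispersion in both groups. The zebrafish RNA replicates themselves spread unequally (chi-square per gene 97.8 in morphants and 8.27 in wild type), so the simulated rates need not hold for them. In the zebrafish RNA simulation of 19451 genes, edgeR recovered 43% of genes changed by a log2 of 1 and 89% at a log2 of 2, with 19 false calls (12.6% of calls). The mouse simulation of 14578 genes recovered 97% and 100%, with 13 false calls (6.19%). The ATAC simulation of 76605 windows recovered 35% and 95% with limma-voom, with 292 false calls (69.2% of calls), and 15% and 87% with edgeR, with 63 false calls (38.2%).

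Replicates were checked for identity by a chi-square test of their counts over genes. The chi-square per gene was 97.8 between the morphant libraries, 8.27 between wild-type libraries, 1.63 at E14.5 and 1.90 at E9.5, with p = 0 to machine precision in each pair. Each pair was kept as 2 libraries, as its labels give it, although the test cannot tell separate pools of embryos from 1 pool. Alternatives tried were limma on log2 TPM with pseudocounts of 1, 0.1 and 5, with and without an intensity trend and with a robust prior, median ratio and quantile scaling, no filter and a filter at 5 TPM, DESeq2 1.42.0, a replicate block and leaving out each library. For ATAC they were other window sizes, thresholds, scalings and duplicate rules, thinning to 11846137 read ends, limma with a trend, and scaffolds included. Library totals, edgeR with a robust prior, the zebrafish dispersion in the mouse test, a length correction, a crossed block, counts of 2-fold differences, lists on log2(TPM + 1), edgeR for ATAC, 1 read end per position and strand, and chromosome 4 left out were added after the data were seen. Gene families in the closing observations were also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.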

Results

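Messenger RNA of whole embryos was sequenced in zebrafish at 24 hours post fertilization (hpf) and in CD1 mice at embryonic stages E9.5 and E14.5, and open chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts accessible DNA, in 24 hpf zebrafish. Zebrafish were either wild type or had been injected with morpholinos (antisense oligonucleotides that block translation or splicing) against tet1, tet2 and tet3, the genes of the Tet enzymes that oxidise 5-methylcytosine. Each of the 6 groups held 2 libraries. Estimated read counts were 40395985 and 44162867 in the morphant RNA libraries and 35295600 and 37611788 in the wild-type ones. The mouse libraries held 46804727 and 44333423 at E9.5, and 42184159 and 35239529 at E14.5. The ATAC libraries held 42001300 and 21891104 read ends in morphants, and 77436659 and 12834672 in wild type. The labels do not say that replicates came from separate clutches or litters, so each p-value measures only the spread between these samples, which may be technical. Bisulfite and Tet-assisted bisulfite libraries of zebrafish, Xenopus and mouse were not analysed here.

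The mouse comparison asked which transcripts differed between the pharyngula, the stage at which vertebrate embryos resemble each other most, and a fetus with formed organs. Between E9.5 and E14.5 transcripts of differentiated tissues rose, among them those of liver, skeletal muscle, neurons, cartilage, connective tissue, lens and definitive blood. Transcripts of pluripotency and early embryo genes, the tailbud, the cell cycle and glycolysis fell. These groups are gene lists. Camera called 0 lists with the correlation between genes estimated from these libraries, a setting that could hardly call any list with so few libraries. Whole embryos were sequenced, so a list's name does not show the tissue in which a transcript rose or fell. Of 14578 genes tested with edgeR, 13118 passed an adjusted p of 0.05, with 6657 higher and 6461 lower at E14.5. Of the 5339 calls of 2-fold or larger differences 3627 were higher and 1712 lower, a balance that was lost with quantile normalization (2167 higher and 2222 lower; 5591 and 7497 among all calls). The libraries of the 2 stages did not overlap for 94.7% of the tested genes, where chance gives 33.3%.

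Ranked by fitted log2 difference, the 10 highest called genes reaching 5 TPM at E14.5 had no read at E9.5, so each fold is a lower bound against a floor of 3 counts over the group and their order against other genes is not established. Cryga, a gamma-crystallin of the lens fibre, reached 134 ± 1.43 TPM (SD, n = 2), at least 1280-fold higher. The other lens crystallins in this group were Cryba4 at 24.5 ± 1.7 TPM (at least 311-fold) and Crygf at 27.02 ± 2.83 TPM. Cryga and Crygf belong to a family of near-identical copies whose reads could be split between them, so their separate levels are uncertain. Kera, the cornea proteoglycan keratocan, reached 14.7 ± 0.777 TPM (at least 464-fold), and the extracellular matrix gene Tnn, tenascin N, reached 5.29 ± 0.00257 TPM (at least 509-fold). Marco, a scavenger receptor of macrophages, reached 14.8 ± 0.263 TPM (at least 465-fold), and the neutrophil gene S100a8 reached 41.6 ± 1.04 TPM (at least 238-fold). Kcnj8, a subunit of ATP-sensitive potassium channels, reached 13.4 ± 0.52 TPM (at least 477-fold), Lypd3 14.2 ± 0.965 TPM (at least 371-fold) and Acox2, a peroxisomal oxidase, 6.03 ± 0.593 TPM (at least 286-fold).

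The 10 lowest called genes by fitted log2 difference included early developmental regulators. Lin28a, an RNA-binding repressor of let-7 maturation, fell from 272 ± 4.85 to 0.523 ± 0.0868 TPM (SD, n = 2), a log2 difference of -8.98. Prtg fell from 104 ± 1 to 0.495 ± 0.0738 TPM (log2 -7.68), and Hoxb1, which patterns the hindbrain, from 30.8 ± 1.82 to 0.159 ± 0.135 TPM (log2 -7.60). Cdx4, a tailbud homeobox gene, fell from 17.1 ± 0.332 to 0.0113 TPM (log2 -10.08) and Foxi2 from 11.5 ± 0.876 to 0.0475 TPM (log2 -7.84). The E14.5 libraries held 1 and 0 reads of Cdx4 and 2 and 3 of Foxi2, so the sizes of these 2 falls are uncertain. Etv2, which specifies endothelial and blood progenitors, fell from 7.12 ± 0.183 TPM to no reads, at least 89.5-fold lower, and Nkx2-6, a pharyngeal and cardiac homeobox gene, from 7.38 ± 0.431 TPM to no reads, at least 101-fold lower. For the ribosomal protein gene Rps27 (402.6 ± 38.4 TPM to no reads, at least 1040-fold lower), Zbed6, which lies inside another gene (5.59 ± 0.144 TPM, at least 349-fold), and Gm37988 (25.3 ± 3.49 TPM, at least 246-fold), reads could be shared with copies or overlapping genes. Their levels are uncertain.

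The genes of the liver rose, with 43 of 47 measured members higher, 3 lower and 1 not called (camera adjusted p = 1.13e-50; adjusted p = 0.226 with an estimated correlation). Alb, serum albumin, rose from 2.72 ± 0.0527 to 3901 ± 77.8 TPM (n = 2), and Serpina6, corticosteroid-binding globulin, from 0.604 to 731 ± 1.81 TPM. The plasma protein genes Apoh and Ahsg had log2 differences of 10.49 and 10.30. Definitive globins rose and primitive globins fell. All 4 definitive genes were higher, with Hba-a1 at 2422 ± 147 and then 51968 ± 2774 TPM, Hba-a2 at 2438 ± 12.2 and then 49241 ± 2083 TPM, Hbb-bs at 37.7 ± 2.48 and then 33339 ± 118 TPM, and Hbb-bt rising by 10.25 on the log2 scale. All 3 primitive genes were lower, Hbb-bh1 falling from 6127 ± 32 to 43.3 ± 5.07 TPM, Hba-x from 5587 ± 153 to 177 ± 10.1 TPM, and Hbb-y from 5628 ± 40.6 to 1683 ± 32.6 TPM. Globin copies share sequence, so reads could pass between them. The lists of 3 and 4 globins were too short for camera.

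**Figure D1:**
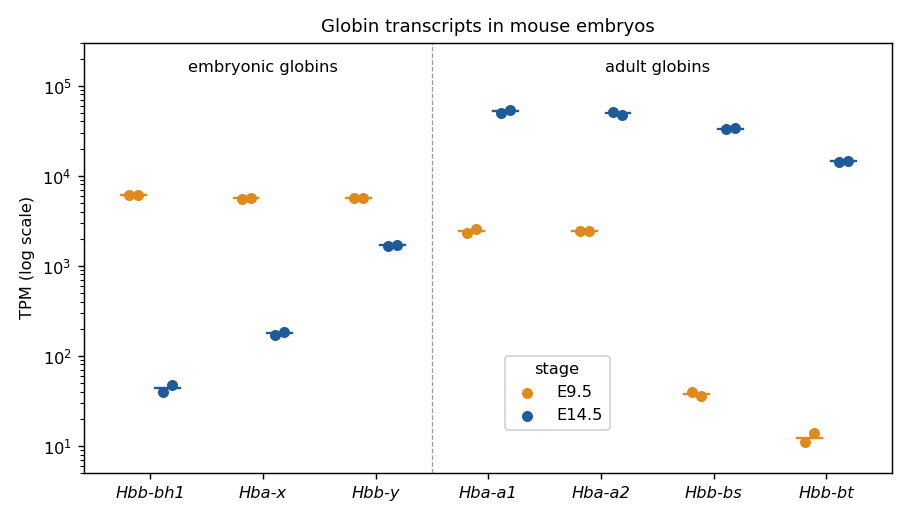
TPM of each globin gene in each mouse library on a log10 axis, by stage, with a point for each of the 2 libraries of a stage and a bar at their mean. The 3 primitive globins were lower and the 4 definitive globins higher at E14.5 in both libraries.

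Genes of other blood lineages rose as well. Of 35 erythroid genes 33 were higher and 2 lower (adjusted p = 7.88e-22; adjusted p = 0.226 with an estimated correlation), with the blood group gene Rhd rising from 3.42 ± 0.3 to 124 ± 1.45 TPM and Bcl11a, a repressor of embryonic globins, from 0.274 to 18.1 ± 0.535 TPM. Car1, a carbonic anhydrase, had no read at E9.5 and was at least 100-fold higher. Of 37 myeloid and lymphoid genes 36 were higher and 1 lower (adjusted p = 7.69e-11; adjusted p = 0.259 with an estimated correlation). Besides S100a8, the granule protein genes Ngp (12.4 ± 0.0199 TPM at E14.5, at least 230-fold), Ltf (at least 153-fold) and Elane (at least 149-fold) had no read at E9.5. Endothelial genes were divided, with 9 of 24 higher, 10 lower and 5 not called (camera direction down, adjusted p = 0.994; adjusted p = 0.994 with an estimated correlation). Pecam1, the endothelial adhesion molecule, rose from 18.8 ± 0.537 to 40.1 ± 1.79 TPM, Robo4 rose by 1.90 and Vwf by 1.70 on the log2 scale, while Etv2 fell. Scaled by library totals, 11 endothelial genes were higher and 9 lower.

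Muscle, skeleton and skin genes rose. Of 53 skeletal muscle genes 51 were higher, 1 lower and 1 not called (adjusted p = 2.79e-45; adjusted p = 0.226 with an estimated correlation). Ckm, muscle creatine kinase, had a log2 difference of 10.31, the myosin heavy chains Myh4 and Myh8 had 9.89 and 9.34, and the myogenic factor Myod1 rose from 0.174 to 52.1 ± 1.15 TPM (n = 2). Of 36 cartilage and bone genes 33 were higher, 2 lower and 1 not called (adjusted p = 1.37e-16; adjusted p = 0.226 with an estimated correlation). Matn1, matrilin of cartilage, rose from 0.128 to 41.6 ± 0.914 TPM, and Col10a1, of hypertrophic chondrocytes, to 13.0 ± 0.354 TPM. The bone matrix genes Ibsp and Dmp1 rose by 7.55 and 8.02 on the log2 scale. Of 39 connective tissue and matrix genes 35 were higher, 2 lower and 2 not called (adjusted p = 8.9e-47; adjusted p = 0.226 with an estimated correlation), with the tendon gene Tnmd at a log2 difference of 8.61, Ogn at 8.50, the elastin gene Eln at 7.14 and Col6a3 at 6.75. Of 31 epidermal and keratin genes 25 were higher, 5 lower and 1 not called (adjusted p = 4.28e-11; adjusted p = 0.259 with an estimated correlation). Krt4 had a log2 difference of 10.47, Krt1 reached 137 ± 1.19 TPM, the desmosomal gene Dsg1a rose by 8.79 on the log2 scale, and Ly6d, with no read at E9.5, was at least 110-fold higher. Keratin paralogs can share reads.

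In the nervous system, neuronal and glial genes rose. Of 48 genes of differentiated neurons 45 were higher and 3 lower (adjusted p = 1.56e-28; adjusted p = 0.226 with an estimated correlation). The neuronal transcription factor genes Neurod6 and Neurod2 rose by 9.55 and 9.47 on the log2 scale, Neurod6 to 33.0 ± 0.203 TPM (n = 2), and the secretory vesicle genes Scg2 and Syt4 by 7.01 and 6.93 on the log2 scale. Of 22 glial genes 18 were higher and 4 lower (adjusted p = 6.61e-05; adjusted p = 0.259 with an estimated correlation), with S100b, Bcan, Gfap and Aldh1l1 rising by 7.33, 6.32, 5.96 and 5.23 on the log2 scale. Of 24 eye, retina and lens genes 22 were higher and 2 lower (adjusted p = 1.2e-07; adjusted p = 0.259 with an estimated correlation). Besides Cryga, Cryba4 and Crygf, the alpha-crystallin gene Cryaa rose from 0.177 ± 0.0775 to 191 ± 2.26 TPM. Neural progenitor genes were not called as a list, with 13 of 38 higher, 22 lower and 3 not called (adjusted p = 0.0984; adjusted p = 0.461 with an estimated correlation). Sox2, a marker of progenitors, fell from 93.7 ± 2.76 to 16.7 ± 0.102 TPM, Sox3 from 41.2 ± 3.69 to 4.55 ± 0.424 TPM, and Pax5 and Neurog1 had log2 differences of -3.26 and -2.84. Of 21 neural crest and pigment genes 7 were higher, 12 lower and 2 not called (adjusted p = 0.33; adjusted p = 0.734 with an estimated correlation). The melanocyte genes Dct and Pmel rose by 5.80 and 3.61 on the log2 scale, while Msx1 fell from 65.4 ± 3.1 to 11.2 ± 0.703 TPM and Pax3 fell by 3.17 on the log2 scale.

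Early embryonic programs fell. Of 19 tested genes of the pluripotency and early embryo list 17 were lower and 2 higher (camera adjusted p = 1.38e-16, and 0.226 with an estimated correlation). The list shares members such as Cdx4 with the somite and tailbud list, so the falls of these lists are not independent. Besides Lin28a and Cdx4, Sall4 fell from 56.6 ± 1.38 to 1.005 ± 0.0505 TPM and Trim71 from 36.1 ± 0.0429 to 1.01 ± 0.0523 TPM (n = 2). Of 29 somite and tailbud genes 27 were lower and 2 higher (adjusted p = 1.93e-05; adjusted p = 0.266 with an estimated correlation), including T, the brachyury gene, from 22.0 ± 0.254 to 0.641 ± 0.1 TPM and the presomitic mesoderm gene Msgn1 to 0.0833 TPM (log2 -7.05). Nkx1-2 fell by 5.08 on the log2 scale. Of 38 Hox genes 26 were lower, 8 higher and 4 not called (adjusted p = 0.0114; adjusted p = 0.259 with an estimated correlation). Posterior genes Hoxc12, Hoxc13 and Hoxd12 were among those that rose, by 5.52, 5.19 and 3.77 on the log2 scale, while Hoxb1 fell. Of 19 Hedgehog pathway genes 13 were lower and 6 higher (adjusted p = 0.0114; adjusted p = 0.369 with an estimated correlation). Ptch1, the receptor, fell from 55.03 ± 0.589 to 16.8 ± 0.419 TPM and Shh, a ligand, to 2.52 ± 0.127 TPM. Nkx6-1 and Foxa2 had log2 differences of -3.59 and -1.75. On log2 TPM the Hedgehog call was lost with a pseudocount of 0.1 (adjusted p = 0.0516) and of 5 (adjusted p = 0.0502).

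Cell cycle and glycolysis genes fell. Of 70 cell cycle genes 65 were lower and 5 higher (adjusted p = 3.69e-14; adjusted p = 0.226 with an estimated correlation). The spindle checkpoint kinase gene Bub1 fell from 106 ± 3.04 to 28.3 ± 0.228 TPM (n = 2), Bub1b from 133 ± 0.708 to 46.8 ± 0.305 TPM and the replication origin gene Orc1 by 1.42 on the log2 scale, while E2f2 rose from 9.28 ± 0.518 to 54.2 ± 0.739 TPM. Of 25 hypoxia and glycolysis genes 19 were lower, 5 higher and 1 not called (adjusted p = 2.51e-09; adjusted p = 0.226 with an estimated correlation). The glucose transporter gene Slc2a3 fell from 286 ± 1.31 to 23.6 ± 1.2 TPM, the pyruvate kinase gene Pkm from 3360 ± 76.3 to 827 ± 3.39 TPM and the hexokinase gene Hk2 by 2.44 on the log2 scale, while Ndrg1 rose by 2.23.

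Among the Tet enzymes, Tet3 had the highest level at both stages. Tet1 (ENSMUSG00000047146) fell from 4.87 ± 0.0236 to 2.46 ± 0.00171 TPM (n = 2), a log2 difference of -0.93 with an SE of 0.0467 and an edgeR adjusted p of 4.69e-10. Tet2 (ENSMUSG00000040943) rose from 3.93 ± 0.0776 to 5.41 ± 0.0551 TPM, a log2 difference of 0.52 with an SE of 0.0486 and an adjusted p of 3.41e-07, but its sign was reversed, to -0.26, with quantile normalization, and it was not called with the dispersion of the zebrafish libraries (adjusted p = 0.0754). Tet3 (ENSMUSG00000034832) fell from 19.8 ± 0.0963 to 15.9 ± 0.334 TPM, a log2 difference of -0.26 with an SE of 0.0267 and an adjusted p of 8.35e-07. This call was also lost with the zebrafish dispersion (adjusted p = 0.387). Of 21 genes of the DNA methylation machinery 9 were higher, 11 lower and 1 not called (adjusted p = 0.139; adjusted p = 0.451 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase, fell from 38.97 ± 0.159 to 6.20 ± 0.274 TPM and Mbd4, a thymine glycosylase, to 6.56 ± 0.0962 TPM (log2 -1.40). Apobec2, a muscle gene of the cytidine deaminase family, rose from 10.5 ± 0.318 to 71.3 ± 1.71 TPM and Gadd45b from 3.99 ± 0.219 to 17.3 ± 1.24 TPM.

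Other signalling lists were divided. Of 58 Wnt pathway genes 20 were higher, 34 lower and 4 not called (adjusted p = 0.0961; adjusted p = 0.266 with an estimated correlation), with 21 higher when adjusted over the list alone. Wnt1 fell from 10.3 ± 0.451 to 0.239 ± 0.0548 TPM, Wnt8b from 4.01 to 0.480 TPM and Fzd3 from 20.5 ± 0.219 to 3.21 ± 0.0587 TPM, and Wif1, a secreted inhibitor, rose by 4.24 on the log2 scale. The Wnt list was called without a filter on low values (adjusted p = 0.0404). Of 29 Notch pathway genes 9 were higher, 19 lower and 1 not called (adjusted p = 0.0705; adjusted p = 0.451 with an estimated correlation), and the Notch list was called without the filter (adjusted p = 0.0246) and on log2(TPM + 1) (adjusted p = 0.0495). The target Hes5 fell from 48.0 ± 0.93 to 10.5 ± 0.551 TPM, and the somite clock gene Hes7, Hes3 and Dll3 had log2 differences of -2.31, -7.58 and -1.67. Of 50 TGF-beta and BMP genes 24 were higher, 23 lower and 3 not called (adjusted p = 0.734; adjusted p = 0.743 with an estimated correlation). Gdf5, a joint marker, rose by 7.08, Ltbp3 by 4.48, Inhbb by 4.43 and Ltbp2 by 3.86 on the log2 scale. With quantile normalization 18 of the 50 were higher and 28 lower. Of 24 imprinted genes 15 were higher, 7 lower and 2 not called (adjusted p = 0.0705; adjusted p = 0.266 with an estimated correlation; fry adjusted p = 0.00052), and the list was called when any 1 library was left out (adjusted p = 0.0193 to 0.0430) or with the replicate number as a block (0.0257). Members that rose included Cdkn1c, a cell cycle inhibitor, from 175 ± 9.36 to 836 ± 32.6 TPM, Dcn from 6.37 ± 0.18 to 279 ± 7.39 TPM, and Rtl1 and Usp29 with log2 differences of 3.16 and 2.87.

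Of 30 heart genes 12 were higher, 16 lower and 2 not called (adjusted p = 0.192; adjusted p = 0.369 with an estimated correlation). Myl7, the atrial myosin light chain, fell from 493 ± 25.4 to 49.4 ± 0.0777 TPM and Sln, sarcolipin, rose from 0.194 to 126 ± 0.592 TPM, while Hand1 and Tbx20 had log2 differences of -4.64 and -2.98. Of 19 kidney and urogenital genes 9 were higher and 10 lower (camera adjusted p = 0.0984, and 0.303 with an estimated correlation). The endocytic receptors Cubn and Lrp2 had log2 differences of -4.05 and -3.68, and the steroidogenic genes Cyp11a1 and Hsd3b1 had 5.23 and 3.87. Cubn is also on the placenta, yolk sac and decidua list, so its fall need not be one of kidney. Of 15 gut epithelium genes 9 were higher and 6 lower; camera gave a downward direction (adjusted p = 0.679; adjusted p = 0.734 with an estimated correlation) against a median log2 of 0.88 and a mean of 1.09. The fatty acid-binding genes Fabp1 and Fabp2 rose by 7.69 and 3.60, Cdh17 by 6.73 and Lgals4 by 4.34. With quantile normalization 7 gut genes were higher and 7 lower. Of 10 pancreas genes 7 were higher, 2 lower and 1 not called (adjusted p = 0.161; adjusted p = 0.369 with an estimated correlation), with the digestive enzyme gene Ctrb1 at least 135-fold higher and Chgb and the somatostatin gene Sst rising by 4.39 and 3.43. Of 8 lung genes 6 were higher, 1 lower and 1 not called (adjusted p = 0.298; adjusted p = 0.698 with an estimated correlation), with the surfactant gene Sftpc rising by 6.47, Cldn18 by 5.44 and Abca3 by 1.68 on the log2 scale. Napsa rose by 1.75, but its sign was reversed with quantile normalization (log2 -0.13), where 3 lung genes were higher and 1 lower. Of 5 germ cell genes 4 were higher and 1 not called (adjusted p = 0.668; adjusted p = 0.744 with an estimated correlation), with Dmrtb1 rising by 2.84 and Nanos3 by 1.81 on the log2 scale, the call of Nanos3 being lost with quantile normalization (adjusted p = 0.281). Sycp3 and Tdrd1 rose by 1.42 and 1.16 but were reversed with quantile normalization (log2 -0.32 and -0.42), where 1 germ cell gene was higher and 3 lower. The share of male embryos may differ between the stages, so differences of germ cell and steroidogenic genes need not reflect stage alone.

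The list of placenta, yolk sac and decidua markers, which tests for extraembryonic and maternal tissue, had 7 of 15 members higher, 7 lower and 1 not called. Camera called it up (adjusted p = 0.0255; adjusted p = 0.259 with an estimated correlation), whereas its median log2 was -0.03 and its mean -0.19, and the call was lost on log2(TPM + 1) (adjusted p = 0.754). Afp, alpha-fetoprotein, which fetal liver also makes, rose from 221 ± 4.74 to 3378 ± 43 TPM (n = 2), while Apoa4 fell from 13.8 ± 0.501 to 0.274 TPM and Hand1 and Cubn fell.

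**Figure D2:**
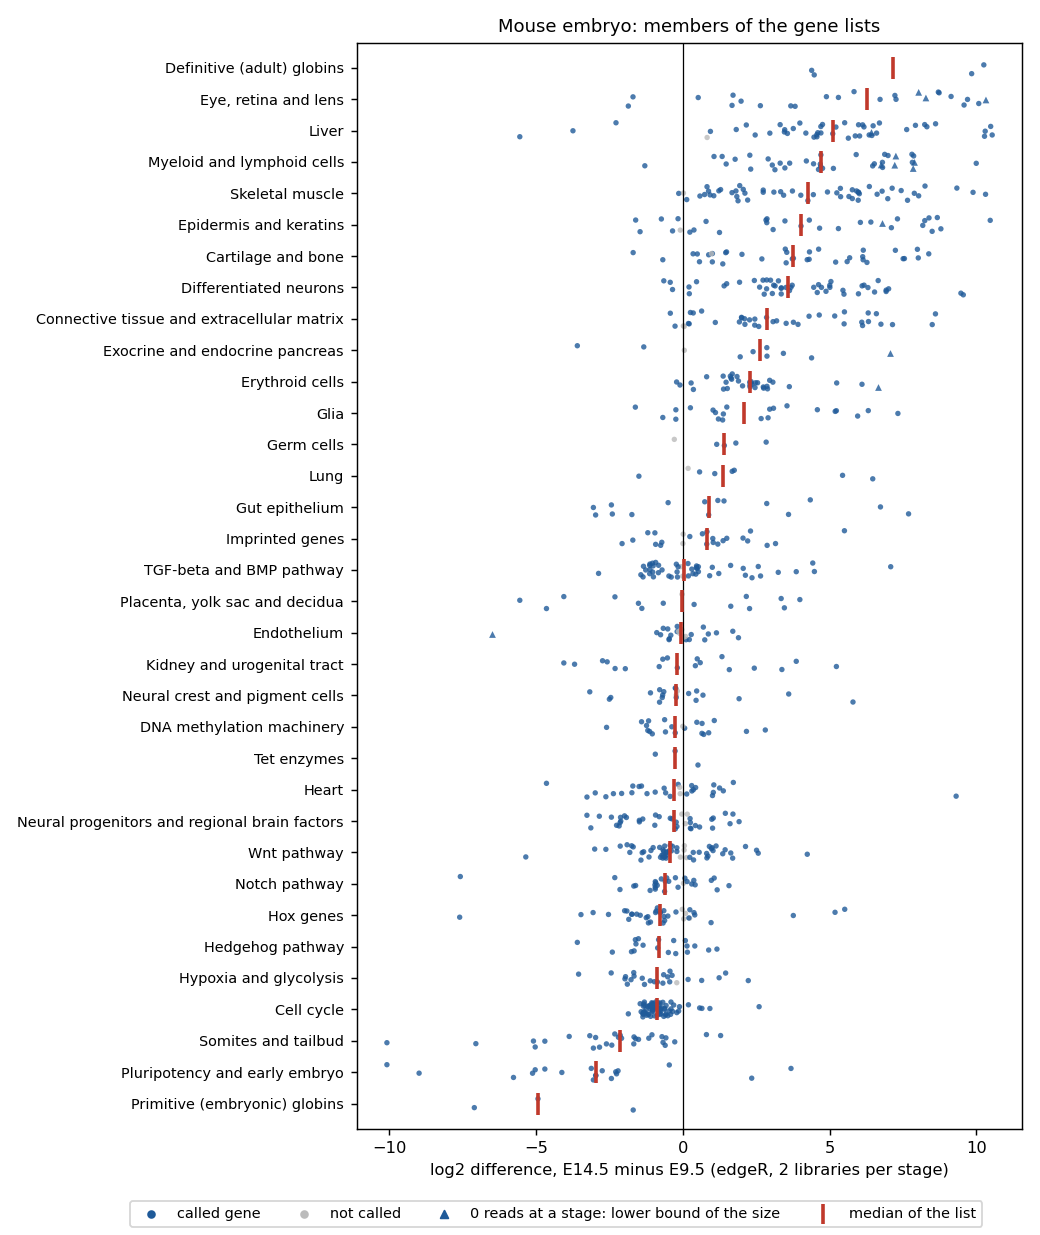
Log2 difference (E14.5 minus E9.5) of each tested member of the mouse gene lists, 1 line per list, with called genes in blue, other genes in grey, triangles for genes without reads at 1 stage at their lower bound, and a red bar at each list's median. Liver (43 of 47 higher) and skeletal muscle (51 of 53 higher) lay mainly above 0 and the cell cycle list (65 of 70 lower) mainly below it.

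Of the 31 mouse lists long enough for camera, 17 passed, 11 up and 6 down. Only members with a mean of at least 1 TPM were tested. These were 10 of 27 on the pancreas list, 8 of 15 for lung, 5 of 23 for germ cells and 15 of 35 for placenta. They were 37 of 53 for myeloid and lymphoid cells and 24 of 36 for the eye. A member without reads at a stage was tested only if it was high enough at the other. Shares of higher or lower members are therefore partly shaped by this filter. With the correlation between genes estimated from these 4 libraries camera called 0 lists (4 at an unadjusted p under 0.05), where 17 had passed with the preset correlation and fry, which tests whether a list moves one way on balance, called 31. The estimated setting tests each list against the spread of only 4 libraries and could hardly call any. Under it the unadjusted camera p of the liver list went from 3.64e-52 to 0.0371. Its 0 calls therefore do not decide whether a list moved. Counts of members adjusted over the list alone were identical for the lists other than Wnt. The coefficient of variation between replicates of a stage was 1.93%, and the count of called genes was 8453 with the larger dispersion of the zebrafish libraries. The median log2 difference of all genes was 0.012, and was 0.131 when scaled by library totals and -0.152 with quantile normalization.

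The zebrafish comparison asked which transcripts differed in embryos injected with morpholinos against the Tet genes. Morphants differed from wild type in 1320 of 19451 tested genes (edgeR, adjusted p under 0.05), 792 higher and 528 lower in morphants. No group with a control morpholino was among those used, here or in the ATAC comparison. Effects of the injection itself therefore cannot be told apart from those of losing Tet enzymes, and that loss was not checked. Of these, 815 differed by 2-fold or more, 546 of them higher. Genes called higher had a median length of 1752.5 bp and genes called lower 2417.5 bp, against 1966 bp over all tested genes. With a correction for length 2165 genes were called, 55.7% of them higher, including 1279 of the 1320. Among called genes with non-overlapping groups and at least 5 TPM in the higher group, the 2 highest by log2 difference were ENSDARG00000096720, at 114.9 ± 26.1 TPM in morphants against 1.86 ± 0.255 in wild type (n = 2; log2 6.19, SE 0.40, edgeR adjusted p = 0.00892), and ENSDARG00000086374, at 41.9 ± 5.97 TPM against 0.924 and 1.18 in the wild-type libraries (log2 5.56, SE 0.37, adjusted p = 0.00892). The 2 lowest by the same rule were ENSDARG00000100241, which had no read in morphants against 15.5 ± 1.82 TPM in wild type, at least 39.8-fold lower (adjusted p = 0.0204), and ENSDARG00000100628, which fell from 5.24 ± 0.418 to 0.569 ± 0.0835 TPM (log2 -2.90, SE 0.57, adjusted p = 0.0453), a call that rested on 2 reads in each morphant library and 15 and 14 in the wild-type libraries, and that was lost with DESeq2 (adjusted p = 0.143) and without wild-type replicate 1 (adjusted p = 0.106). The files give zebrafish genes by identifier only, so tet1, tet2 and tet3 transcripts and gene lists were not analysed here.

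All 1320 called genes had both morphant libraries on one side of both wild-type libraries, as had 62.3% of tested genes, where chance gives 33.3%. The count of calls depended on the libraries used, and was 11221 without morphant replicate 1, 5700 without morphant replicate 2, 958 without wild-type replicate 1 and 734 without wild-type replicate 2, fits in which the spread came only from the group with 2 libraries and the lone library was assumed to vary like them. Across genes, the rank correlation of TPM was 0.969 between the morphant libraries and 0.990 between the wild-type libraries, with morphant replicate 2 farther from wild type (0.921 and 0.931) than morphant replicate 1 (0.959 and 0.961). DESeq2 called 2858 genes, limma on log2(TPM + 1) 381 and edgeR scaled by library totals 221, and the share of calls that were higher in morphants was 60% in the edgeR result, 55.2% in DESeq2, 52.5% with quantile normalization, 50.2% and 51.5% without morphant replicate 1 or 2, 71.4% in limma, where the median log2 of all genes was -0.196 instead of 0.0012, and 84.2% with library totals.

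**Figure D3:**
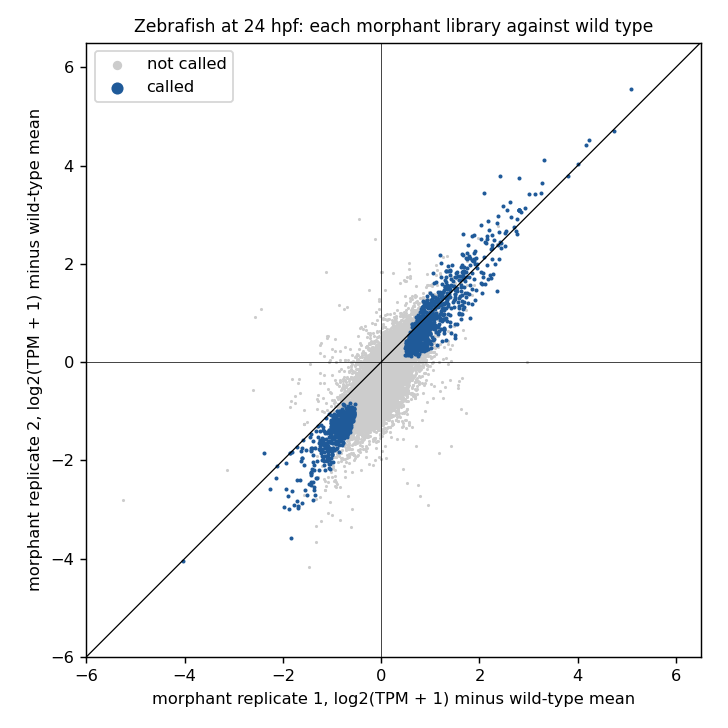
Difference in log2(TPM + 1) from the mean of the wild-type libraries for each tested zebrafish gene in morphant replicate 1 (horizontal) and morphant replicate 2 (vertical), with called genes in blue, other genes in grey and a diagonal line of equality. The 792 higher and 528 lower genes lay on the same side of 0 in both libraries.

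The ATAC comparison asked whether accessible chromatin differed in embryos injected with those morpholinos. The share of reads in accessible windows did not separate the groups. Individual windows differed in both directions. Windows called with a log2 difference between -3 and -1 outnumbered those between 1 and 3, whereas 189 of 198 tested windows were called between 3 and 4 and 67 of 87 above 4, against 69 of 257 between -4 and -3 and 6 of 432 below -4. On chromosomes 1 to 25, 76605 windows of 500 bp had at least 5 times the uniform read level. They held 32.0% and 34.4% of read ends in the morphant libraries (mean 33.2 ± 1.67, n = 2) and 37.5% and 31.7% in the wild-type libraries (34.6 ± 4.06), a difference of -1.41 points (exact permutation test, two-sided, p = 1, where the smallest possible p is 0.33). The difference was 1.77 points without wild-type replicate 1.

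Limma-voom called 30450 windows, 14775 more and 15675 less accessible in morphants. In data simulated with 200 changed windows it made 292 false calls among 76605 windows, 69.2% of its calls there. That share depends on how many windows were changed, so it does not give the false share among the 30450 calls. Of the 9724 windows with a 2-fold or larger difference, 3022 were more and 6702 less accessible. This balance depended on the setting. It was 12461 more and 14720 less in 200 bp windows, and 3884 and 5581 when scaled to reads in accessible windows. Scaled to total reads it was 2203 and 7620. EdgeR called 11841 windows, 3600 more and 8241 less accessible, including 6980 of the 9724. Limma-voom called 3074 of the 9724 after each library was thinned to the depth of the shallowest. The groups did not overlap in 90.1% of called and 62.0% of tested windows, where chance gives 33.3%. The highest called windows by fitted log2 difference, in the zebrafish build danRer7, were chromosome 7, 75104501 to 75105000 (log2 6.16, SE 1.53, limma adjusted p = 0.0215), chromosome 11, 41588501 to 41589000 (log2 5.88, SE 1.87, adjusted p = 0.0457) and chromosome 23, 2400501 to 2401000 (log2 5.48, SE 1.35, adjusted p = 0.0210). The chromosome 7 window was not called by edgeR (adjusted p = 0.261). It had a log2 of 0.415 without wild-type replicate 1, as it held 2 read ends in that library and 26 in wild-type replicate 2. The chromosome 11 window lost its call with scaling to total reads (limma-voom adjusted p = 0.0774). The lowest were at chromosome 8, 49013501 to 49014000, with 0 read ends in morphants against 290 and 44 in wild type (at least 73.9-fold lower, adjusted p = 0.0369; not called with cyclic loess, adjusted p = 0.667, scaling to total reads, 0.0532, limma with a trend, 0.132, or without morphant replicate 1, 0.184, or 2, 0.0594), and at 2 windows of chromosome 20, 55788001 to 55788500 (log2 -4.70, adjusted p = 0.0408) and 55792001 to 55792500 (log2 -4.52, adjusted p = 0.0459). In both, wild-type replicate 1 alone was high (1532 and 1134 read ends, against 0 and 1 in wild-type replicate 2), the groups overlapped, and edgeR made no call (adjusted p = 0.067 and 0.0718). After thinning all 6 of these windows lost their call. Which genes lie at these positions was not analysed here.

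With a library left out, the spread came only from the other group, and the lone library was assumed to vary like it. Without morphant replicate 1, limma-voom called 0 windows (26518 at an unadjusted p under 0.05) and edgeR also 0 (13397 unadjusted), and without morphant replicate 2 limma-voom called 34669 and edgeR 0 (12711 unadjusted). Without wild-type replicate 1 limma-voom called 11332 windows, of which 18.7% were more accessible in morphants, and edgeR 18981, and without wild-type replicate 2 they called 34578 and 22681; scaling to total reads gave 34.6% more accessible among calls and scaling to reads in accessible windows, where the median window was at 0.102 instead of 0.0189 on the log2 scale, gave 58.1%, against 48.5%.

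**Figure D4:**
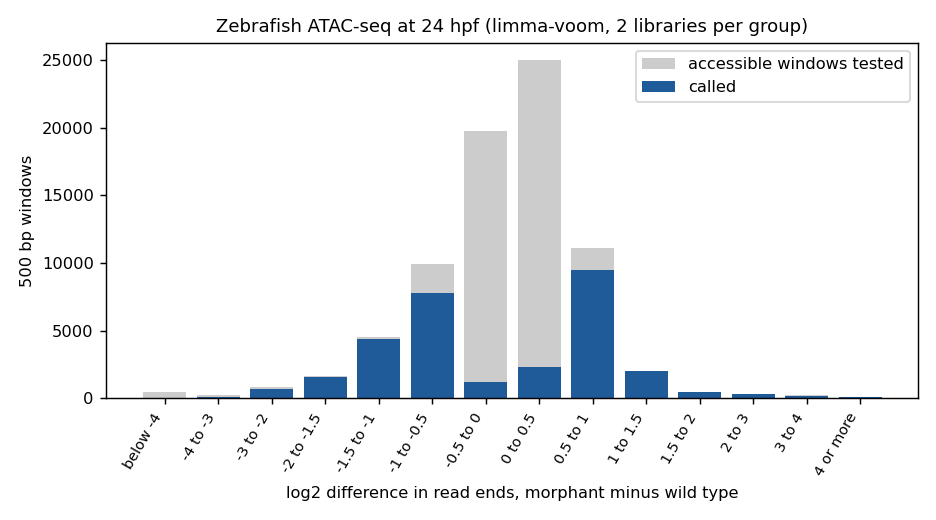
Number of accessible 500 bp windows (vertical axis) in each class of log2 difference, morphant minus wild type, with all tested windows in grey and those called by limma-voom in blue. Called windows of 2-fold or larger difference were less accessible in morphants in 6702 cases and more accessible in 3022.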

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

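Counts of 2-fold differences, library totals, the zebrafish dispersion in mouse, length correction, crossed block, lists on log2(TPM + 1), edgeR for ATAC and 1 read end per position were chosen after the results were seen. Each spread was estimated from 2 libraries per group, or from the other group alone where a library was left out, and the shallowest ATAC library held 12834672 read ends. Not run were the zebrafish gene lists, the tet1, tet2 and tet3 transcripts and another level of summary, for which no table was used, and leaving out windows above 200 times the uniform level, as no 500 bp window reached it in the 4 libraries with duplicates removed (15 of the 200 bp windows did). Where values moved, the cause was not tested.

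Zebrafish calls, 1320, were 381 with limma on log2(TPM + 1), 230 and 603 with pseudocounts of 0.1 and 5, 142 without the trend, 340 with a robust prior, 2243 with quantile normalization, 221 with library totals, 2858 with DESeq2 and 2165 with the length correction. Leaving out 1 library gave 734 (without wild-type replicate 2) to 11221 (without morphant replicate 1), and 5700 without morphant replicate 2. The 2-fold calls, 815, were 318 with limma, 209 and 232 with those pseudocounts, 142 without the trend, 292 with a robust prior, 530 at 5 TPM, where fewer genes were tested, 212 with library totals and 723 to 2892 without 1 library. All 1320 genes kept their sign with the length correction, and 1279 were called.

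Mouse calls, 13118, were 8453 with the zebrafish dispersion and 12427 to 13190 without 1 library. The 2-fold calls, 5339, were 2702 with a pseudocount of 5, 3303 at 5 TPM and 5023 to 5531 without 1 library. Over 142 named genes, 2639 values kept direction and call, 3 lost the call and 4 were reversed, all 4 with quantile normalization: Tet2 (-0.258), Napsa (-0.129), Sycp3 (-0.318) and Tdrd1 (-0.422). Called lists, 17, were 0 with an estimated correlation and 31 with fry, and 18 when any 1 library was left out. The endothelium list changed direction with fry (adjusted p = 0.00577), the block (0.905), the 5 TPM filter (0.756) and without each of 3 of the 4 libraries (0.898 to 0.990 over all 4). The gut list changed direction on log2(TPM + 1) (0.532) and with pseudocounts of 0.1 (0.558) and 5 (0.541).

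ATAC calls, 30450, were 47861 and 17172 in 200 and 1000 bp windows, 14740 at 10 times the uniform level, 5152 after thinning, 13213 with limma-trend, 11841 with edgeR and 14528 with 1 read end per position. Leaving out 1 library gave 0 with limma-voom (without morphant replicate 1; 26518 unadjusted, edgeR 0) to 34669, and 11332 without wild-type replicate 1. The 2-fold calls, 9724, were 27181 and 3952 in 200 and 1000 bp windows, 3374 and 19236 at 10 and 3 times, 3630 after thinning, 4529 with 1 read end per position and 0 (without morphant replicate 1) to 11992 without 1 library. The share of reads, -1.41 points, was -4.23 to 1.77 without 1 library, positive only without wild-type replicate 1, and 0.0138 with 1 read end per position. Over the 6 named windows 58 values kept their call and 31 lost it, none reversed.

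Replicate numbers shared no stated clutch or day. Same-numbered deviations correlated at -0.266 in zebrafish RNA, 0.012 in mouse and -0.015 in ATAC. With the replicate number as a block, calls were 1902, 13169 and 35782, 2-fold calls 1199, 5341 and 10611, and called mouse lists 18, the added one being imprinted genes (adjusted p = 0.0257). A crossed block gave 5182 zebrafish calls.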

Other observations

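Gene families, defined by the start of the symbol, were chosen after the data were examined, as were the test for the processing of wild-type replicate 1 and the regression slopes of the zebrafish RNA libraries, which were chosen after their results were seen. Among 89 families tested in mouse, collagens rose and families of nuclear pores, RNA polymerases, helicases and translation initiation fell from E9.5 to E14.5. Of 40 collagen genes 35 were higher and 4 lower (camera adjusted p = 8.38e-35), with Col1a1, of bone and skin, going from 147 ± 0.54 to 1629 ± 8.1 TPM (n = 2). All 19 nucleoporin genes were lower (adjusted p = 1.97e-07), Nup107 going from 86.04 to 34.4 TPM, with log2 differences from -2.28 (Nup62cl) to -0.42 (Nup210). Of 54 Eif genes 47 were lower and 5 higher (adjusted p = 1.31e-06), and of 34 Ddx genes 32 were lower and 2 higher (adjusted p = 4.56e-06). Of 28 Polr genes 26 were lower and 1, Polr3gl, was higher (log2 1.43; adjusted p = 0.00118), while its paralog Polr3g, the other form of that RNA polymerase III subunit, fell by 1.58 on the log2 scale. These directions held under each scaling tried. With an estimated correlation, a setting that could hardly call any family with so few libraries, the camera adjusted p was 0.651 for each of these families.

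Y-linked genes were lower at E14.5 by different amounts. Uty, Ddx3y, Eif2s3y and Kdm5d had log2 differences of -4.01, -3.53, -3.26 and -1.1, with SEs of 0.136, 0.101, 0.0871 and 0.0439 and edgeR adjusted p-values of 9.11e-12, 1.65e-12, 8.76e-13 and 4.72e-11. Kdm5d was at 5.14 and 5.28 TPM in the E14.5 libraries against 11.6 in both E9.5 libraries, and Ddx3y at 0.890 and 1.06 against 10.9 and 12.4. The sex of the embryos was not part of the comparison. A lower share of males at E14.5 therefore cannot be told apart from lower expression of these genes. A change in that share alone would lower them alike, whereas Kdm5d fell by less, so it need not be the whole of the difference.

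Accessible windows differed between morphant and wild-type ATAC libraries, although wild-type replicate 1 was processed differently. Its processing alone was argued against, since the differences of disjoint pairs (morphant minus wild type, same numbers) correlated at r = 0.567 across windows, which are not independent replicates. That test was chosen after its result was seen, and it leaves open that the processing shaped part of the calls. DNA wholly absent from the fish of a group was argued against for the called windows only. Of those with a 2-fold difference 0.0103% had at most 3 read ends in a group, which is 1 window, on chromosome 8. Windows with a log2 difference below -4 were seldom called (6 of 432), whereas 67 of 87 above 4 were called. This share therefore cannot decide the question for windows that were not called, most of all those lower in morphants. Among 678529 windows of 2000 bp, 67 were nearly empty over the morphant libraries (at most 0.02 of the uniform level) and held at least 0.3 of that level in each wild-type library. The opposite held for 29. A mixed split, with morphant replicate 2 and wild-type replicate 2 nearly empty, gave 70. An effect of the morpholinos stays open as an untested hypothesis, as do a difference in stage or tissue makeup and a shared handling of the libraries of a group, for which the labels give no batch.

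Morphant replicate 2 of the zebrafish RNA-seq lay farther from wild type than morphant replicate 1. The difference between them followed gene length across genes (Spearman rho = -0.361), so a length bias may be part of it. It was not all of it, since after a length correction the spread of replicate 2 from wild type stayed 1.29 times that of replicate 1. Disjoint morphant minus wild-type differences correlated at r = 0.547, but whether replicate 2 carries a stronger form of the same change cannot be told apart from noise, as the regression slope was 0.764 one way and 2.55 the other. A developmental delay or a higher morpholino dose in that library was not tested.

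Mouse replicates of a stage differed by little more than counting error at 100 to 1000 reads, with a chi-square per gene of 1.13 at E14.5 and 1.11 at E9.5, but by more in the most abundant genes (5.68 over 1006 genes and 5.23 over 1424). A candidate explanation is that both libraries of a stage came from 1 pool of RNA, in which case sex-linked genes would match between them. Among Y-linked genes with at least 100 reads in each library the largest log2 ratio between replicates, of Eif2s3y at E14.5, was 0.318 with a counting SE of 0.197, and Uty, with 48 and 23 reads, differed by -0.80 with an SE of 0.366. At E9.5 Ddx3y differed by 0.191 (SE 0.06) and Eif2s3y by -0.106 (SE 0.061), apart by more than counting error. Eif2s3y at E14.5 lay outside the 0.2 set in advance for 1 pool, although its SE spans that limit. It fell short of the 0.5 set in advance for separate pools. Xist, also named in advance, was not found among the gene symbols. Hence 1 pool and separate pools of many embryos cannot be told apart. No biological explanation was tested.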
